A study of Mus musculus with 6 samples.

How the data were processed

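Gene expression was measured on 6 mouse arrays of 45101 probe sets each, 3 of cells labelled CD8aa Tregs and 3 of OT-1 T cells, with 1 column of values per sample. Per the labels' protocols, the cell lines were cultured with their antigen, antigen-presenting cells and IL-2, RNA was extracted with an RNeasy kit, and it was amplified with the Ovation RNA Amplification System V2 and labelled with biotin. Per the submitters' processing notes, the values were made with RMA, whose version was not stated. The values the authors deposited were used as log2 values, although no source used here states the base. The widest probe set spanned 11.37, more than the natural log of a 16-bit scanner range (11.09), which leaves no room for natural logs.

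The deposited log2 values had been centred: the median of every probe set over the 6 arrays lay within 5.0e-07 of 0. No source used here mentions this step. Centring keeps differences between arrays and removes the level of each probe set, so it cannot be read from these values whether a gene was bright or at background, and a fold change against a group at background cannot be bounded. Of the probe sets, 15520 (34.4%) spanned less than 0.1 over the 6 arrays. RMA draws probe sets near background together, so differences that start or end there understate the change. The precision is limited by the number of arrays.

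Groups and replicate numbers came from the sample titles, and the labels give no batch, slide or scan date. Of the probe sets, 64 were array controls and stayed out of the gene tests. A table of the array's annotation gave 1 gene symbol for 34945 of the others and several for 932, and did not list 9160. Symbols were checked by Entrez gene identifier against a RefSeq table of assembly GRCm38.p6, which held the identifiers of 34741 probe sets and changed 0 symbols. No coordinates entered the expression values or the group comparison; the order of genes in that assembly was used for tests of neighbouring genes and of the H2 complex. The mean over all probe sets of a gene was its value, which gave 18193 genes, 9010 of them with more than 1 probe set. Probe sets of a gene often disagreed, and the text gives the range for named genes where it is wide. Genes with near-identical relatives, such as granzymes, class I H2 genes, Klra receptors and Trim30 relatives, can share probes and are uncertain.

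The groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided), and p-values were adjusted by Benjamini-Hochberg over all genes. A gene passed at an adjusted p under 0.05, and a size of at least 1 on the log2 scale (2-fold) was a second threshold. Differences are CD8aa Tregs minus OT-1, with the standard error of the fit. The prior had 0.98 degrees of freedom, so each gene's own spread weighed heavily. In 30 gene lists, members were counted over all genes and with the adjustment over the list alone. Each list was set against all other genes with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether members move one way without comparing them with other genes, were alternatives. Python packages were pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

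The groups, the tests, the lists, the naming rule and most alternatives were chosen before the data were examined. The text names the 6 genes with the largest positive and the 6 with the largest negative difference among those that passed with groups that did not overlap. It names up to 3 members of each list that passed, by size, and a set of T cell genes given in advance. Because levels were removed, 4 planned steps could not be run: taking the brightest probe set of a gene, adding a constant to damp dim probe sets, filtering on mean level, and modelling a trend with intensity. The mean of all probe sets, which was to be tried beside it, took the place of the brightest one. Where no member of a list passed, the rule called for the member with the highest level, and the one with the widest range was named instead. Klrb1c, a gene to be named in any case, was not measured under a single symbol.

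Tested on simulated arrays with the spread of the real genes, the fit called 64% of 100 genes changed by 1 and 92% of 100 genes changed by 2 on the log2 scale, and 10 unchanged genes out of 18193 tested. The changed genes were drawn among those spanning at least 0.1. The simulated noise was normal and independent between genes and arrays. On the real arrays OT-1 replicate 1 departed in many genes together, so these values may not hold there. Alternatives were leaving out each array, the replicate number as a block, array weights, other scalings, other ways to combine or choose probe sets, other thresholds and other set tests. After the data were seen, further ones were added: the widest probe set, a filter on range, robust variances, median centring, and the split of the arrays by their poly-A spike-in controls as a term.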

Results

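Cultured T cells of 2 kinds were compared on 6 arrays, 3 per group. The CD8aa Tregs (replicates 1, 2 and 4) carry the CD8 alpha homodimer, and the series describes them as regulatory and restricted by Qa-1, a class Ib MHC molecule. The OT-1 T cells (replicates 1, 2 and 3) carry a transgenic receptor for an ovalbumin peptide, and the series describes them as CD8aa+ too. The comparison asks how the expression of the regulatory cells differs from that of the OT-1 cells. The labels do not say whether replicates are separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The sample titles give each group a single name with a number, and the labels' protocols speak of cell lines. Each group may thus be repeats of 1 line. Differences may belong to these lines and are not shown for CD8aa Tregs or OT-1 T cells in general.

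The OT-1 arrays were not alike. Across probe sets spanning at least 0.1, which are not independent of each other, OT-1 replicates 2 and 3 correlated at r = 0.855, while OT-1 replicate 1 correlated with them at 0.298 and 0.353. The CD8aa Treg arrays correlated with each other at 0.614 to 0.671. With the CD8aa Treg arrays, OT-1 replicate 1 correlated at -0.623 to -0.441, but centring on the median over the arrays lowers correlations between the groups. Its median absolute difference was 0.181, 0.200 and 0.183 to CD8aa Treg replicates 1, 2 and 4, and 0.205 and 0.189 to OT-1 replicates 2 and 3. The standard deviation of its differences was 0.67, 0.71 and 0.67 to those CD8aa Treg arrays, and 0.56 and 0.54 to those OT-1 arrays. Which group it lay nearer thus depended on the measure. The poly-A spike-in controls are bacterial transcripts that are added to RNA to follow its labelling. They also set OT-1 replicate 1 apart from OT-1 replicates 2 and 3, and placed it with the CD8aa Tregs. The mean of these controls lay between -0.11 and 0.82 on the CD8aa Treg arrays and at 0.49 on OT-1 replicate 1, but at -1.58 and -2.39 on OT-1 replicates 2 and 3. With this split as a term of the fit, a group difference rests on OT-1 replicate 1 as the lone OT-1 array of its side, which is taken to vary as the others do. List counts without OT-1 replicate 1 are given where they differ by more than 1.5 times, and values with the split as a term where they end, turn or add a call. In fits without OT-1 replicate 1 the groups coincide with this split, so group and split cannot be told apart there.

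Among named genes that passed, the largest differences on the lower side in CD8aa Tregs were those of Gzma, Plac8 and Gzmk. On the higher side they were those of Xist, a sex-linked gene, and Gpr15. Gzma and Gzmk, serine proteases of cytotoxic granules, were lower in CD8aa Tregs by a log2 difference of -10.85 ± 0.38 (SE, n = 3 per group; adjusted p = 0.000467) and -8.65 ± 0.58 (adjusted p = 0.00258). Plac8 was lower by -9.53 ± 0.32, the antiviral membrane protein gene Ifitm3 by -6.48 ± 0.52, Pglyrp1, which encodes a peptidoglycan-binding protein, by -5.99 ± 0.16, and Tm6sf1 by -5.77 ± 0.19. On the higher side in CD8aa Tregs stood Xist, the RNA of X inactivation, at 7.72 ± 0.19 (adjusted p = 0.000203; probe sets from 5.29 to 8.99), and Gpr15, a homing receptor of T cells for the large intestine, at 6.14 ± 0.12 (adjusted p = 0.000158). Tmem87a stood at 5.52 ± 0.12, the actin-severing gene Scin at 4.95 ± 0.51, AI506816 at 4.70 ± 0.10, and BC018473 at 5.16 ± 0.15, the last as the mean of probe sets at 0.45 and 9.86.

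Of 18193 genes, 1214 passed (limma, Benjamini-Hochberg), 600 higher and 614 lower in CD8aa Tregs. Of these, 473 differed at least 2-fold, 169 higher and 304 lower. The groups did not overlap in 4246 genes (23.3%, against 10% by chance). Leaving out OT-1 replicate 1 raised the counts to 3129 genes, 1419 higher and 1710 lower, and 953 at least 2-fold, and these held 1163 of the 1214 and 458 of the 473. That fit leaves OT-1 replicates 2 and 3, which correlated at 0.855, as the OT-1 group, and its groups coincide with the spike-in split. The rise thus cannot be read as more differences between the kinds of cell. Leaving out any of the other 5 arrays lowered the counts: to 523, 599 and 697 genes without CD8aa Treg replicates 1, 2 and 4, and to 535 and 564 without OT-1 replicates 2 and 3. At least 2-fold, these fits left 283, 308, 325, 277 and 297 genes. With the spike-in split as a term, 1361 genes passed, 688 of them among the 1214. OT-1 replicate 1 shares a side of that split with the CD8aa Tregs. Of the 953 genes chosen without it, 430 (45.1%) differed at least 2-fold with the same sign between the CD8aa Treg mean and that array (150 of 263 higher, 280 of 690 lower), and 13 did so with the opposite sign. In the same check, the CD8aa Treg arrays gave 0.6% to 0.9% when held out against the other CD8aa Tregs, and OT-1 replicates 2 and 3 gave 89.2% and 92.6%. The gene sets differ, since the 277 and 297 genes behind the last 2 shares were chosen in fits that held OT-1 replicate 1. Such fits favour genes on which that array went with OT-1, so these shares cannot be set directly beside the 45.1%. Of the 65 named genes that passed, 65 kept their sign in the 6 fits with 1 array left out. Their groups did not overlap, so no other outcome was possible. Of the 65, 24 did not pass in at least 2 of these fits. Bach2 and Lag3 did not pass in 2 of the 6, Klrk1, Nod1 and Serpinb9 in 3, and Calr, Gbp3, Il21r, Jun and Tyms in 4. Aim2, Asns, Cd244a, Csf1, Dnajb1, Fdft1, H2-Ab1, Itgax, Pecam1, Rtp4, Slamf7, Tnf, Tnfrsf4 and Zeb2 did not pass in 5. The array named below beside each gene is the one whose loss gave its highest adjusted p. The differences of the 24 genes stayed between 0.82 and 1.19 times those over all arrays. With the spike-in split as a term, 13 of the 65 did not pass: Klrk1, Tyms, Itgax, Fdft1, Il21r, Tnf, Asns, Dnajb1, Calr, Pecam1, Aim2, Nod1 and Gbp3.

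**Figure D1:**
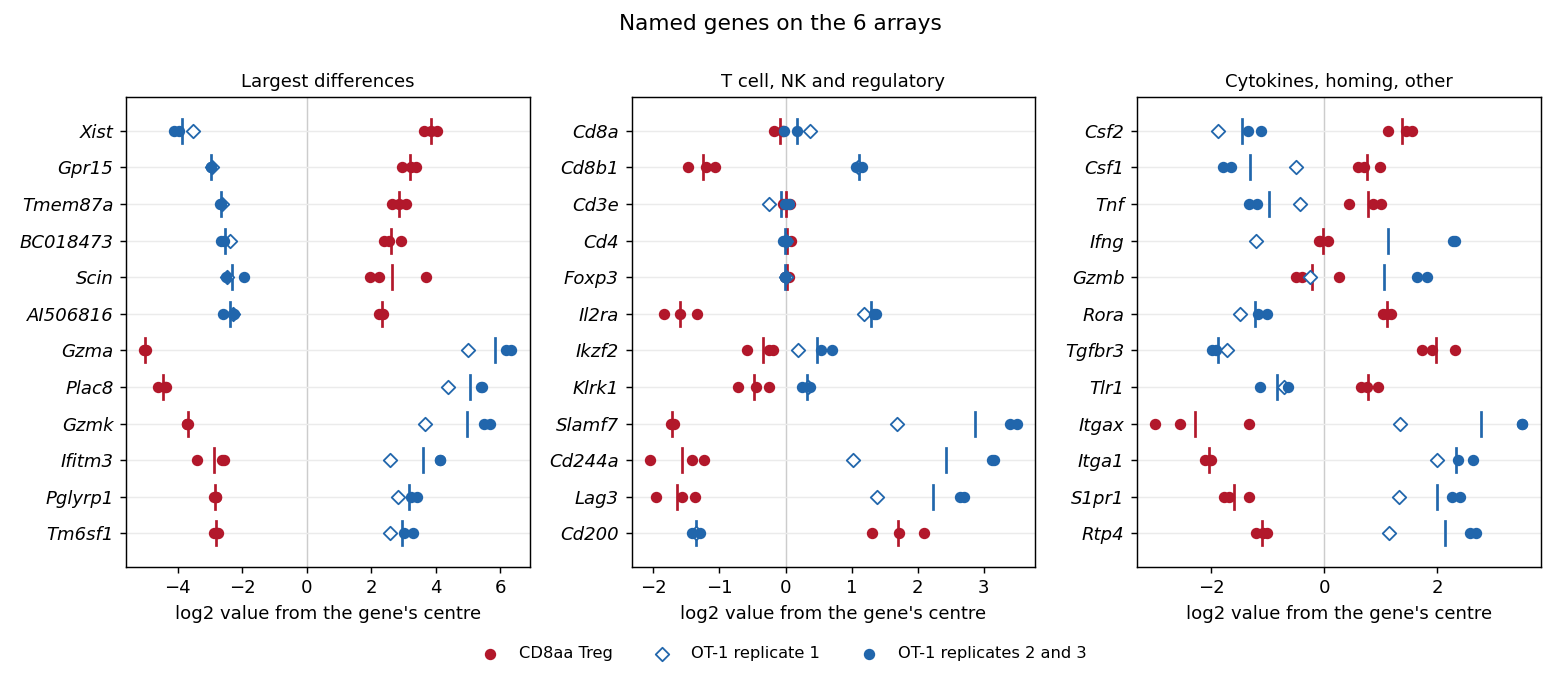
Each point is 1 array's log2 value for a gene, measured from the gene's centre over the 6 arrays, and short lines mark group means (n = 3 per group). Red points are CD8aa Tregs, filled blue points OT-1 replicates 2 and 3, and open diamonds OT-1 replicate 1. The group difference is -10.85 for Gzma and 7.72 for Xist, and OT-1 replicate 1 stands apart from the other OT-1 arrays in Ifng and Gzmb.

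Genes that define T cells went both ways. Cd8b1, the CD8 beta chain, was lower in CD8aa Tregs by -2.36 ± 0.11 (adjusted p = 0.00093), a 5.15-fold difference. Cd8a did not pass at -0.26 ± 0.11 (adjusted p = 0.303), with 5 probe sets from -2.40 to 0.85. Cd3e (0.08) and Cd4 (0.02) did not pass. Among 20 measured genes of the T cell receptor complex and T cell identity, 3 were higher, 3 were lower and 14 did not pass (7 and 4 adjusted over the list alone; 5 and 4 without OT-1 replicate 1). Cd6, a costimulatory receptor, was higher by 1.85 ± 0.08, and Lcp2, the adaptor SLP-76, was lower by -1.37 ± 0.08 over probe sets from -3.02 to 0.27. The list was not shifted (camera adjusted p = 0.797), and its median (0.06) and mean (-0.01) differed in sign. Of 14 CD4 T cell markers, Tnfrsf4, the receptor OX40, was higher at 1.69 ± 0.26, also over the list alone (camera adjusted p = 0.155). Of 6 gamma delta T cell markers, the transcription factor gene Maf was higher at 0.87 ± 0.09 over probe sets from -0.01 to 2.35, also over the list alone (camera adjusted p = 0.189). Maf did not pass with the widest probe set of each gene, with probe sets whose identifiers end in _x_at or _s_at left out, or with the replicate block. Without CD8aa Treg replicate 2, Tnfrsf4 did not pass (adjusted p = 0.115).

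Receptors shared with NK cells were lower where they differed. Of 28 such receptors and adaptors, 0 were higher and 8 were lower (1 and 8 adjusted over the list alone; 1 and 9 at an unadjusted p under 0.05; 0 and 9 without OT-1 replicate 1). Slamf7, a receptor of the SLAM family, was lower by -4.58 ± 0.53, Cd244a (2B4) 15.96-fold (adjusted p = 0.0367), the adhesion receptor Crtam by -1.84 ± 0.16 and Klrk1 (NKG2D) by -0.80 ± 0.13. Camera placed the list lower (adjusted p = 0.0115; adjusted p = 0.424 with an estimated correlation), with a median of -0.003 and a mean of -0.69, and a median of 0.01 without OT-1 replicate 1. Fcer1g, an adaptor of NK and myeloid receptors, did not pass at -0.66 ± 0.52 (adjusted p = 0.66). OT-1 replicate 1 stood at 1.80 for it and the other 5 arrays between -0.03 and 0.11, which the spike-in split as a term restates (-1.82, adjusted p = 0.000823). Without OT-1 replicate 2, Klrk1 did not pass (adjusted p = 0.124), and without CD8aa Treg replicate 1 neither Cd244a (0.132) nor Slamf7 (0.0627) passed.

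Of 22 cytotoxic granule and death ligand genes, 0 were higher and 4 were lower (1 and 7 adjusted over the list alone, 1 and 8 at an unadjusted p under 0.05, 0 and 9 without OT-1 replicate 1). Beside Gzma and Gzmk, the granzyme B inhibitor gene Serpinb9 was lower by -2.13 ± 0.24. Without OT-1 replicate 2, Serpinb9 did not pass (adjusted p = 0.0648). Gzmb did not pass at -1.27 ± 0.63 (adjusted p = 0.378), and without OT-1 replicate 1 it was lower by -1.93 (adjusted p = 0.0169). The median of the list was -0.35 (camera adjusted p = 0.000378; adjusted p = 0.424 with an estimated correlation). It was -0.64 without OT-1 replicate 1, -0.20 without OT-1 replicate 3 and -0.08 with the spike-in split as a term. In this list OT-1 replicate 1 lay at least 1 below both other OT-1 arrays for 9 genes.

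Genes tied to regulatory T cells did not stand higher as a group. Foxp3, the lineage factor of CD4 Tregs, showed no detectable difference (0.02 ± 0.02, adjusted p = 0.787), and the regulatory cytokine genes Il10 (0.01) and Tgfb1 (0.26, adjusted p = 0.123) did not pass, Tgfb1 being higher without CD8aa Treg replicate 2 (0.33, adjusted p = 0.0403). Foxp3 (-0.016 to 0.054) and Il10 (-0.024 to 0.011) spanned less than 0.1 over the 6 arrays. Both may lie at background in both groups, so equal expression is not shown. Il2ra, the IL-2 receptor alpha chain, was lower in CD8aa Tregs by -2.89 ± 0.14 (adjusted p = 0.000958), the checkpoint receptor Lag3 by -3.88 ± 0.42 and Fgl2 by -2.78 ± 0.13. Of 24 such genes, 3 were higher and 5 lower (5 and 9 adjusted over the list alone; 5 and 12 without OT-1 replicate 1). The median of this list was -0.14 (camera adjusted p = 0.0352; adjusted p = 0.503 with an estimated correlation). It was -0.26 without OT-1 replicate 1 and 0 with the spike-in split as a term. The call ended in 3 of the 6 leave-one-out fits (highest adjusted p = 0.152, without OT-1 replicate 2) and with the spike-in split as a term (adjusted p = 0.832). It also ended under 3 of 4 other scalings (adjusted p = 0.0561 to 0.09), with the widest probe set of each gene (0.0879) and with genes spanning at least 0.1 (0.0528). Ikzf2 (Helios) and the integrin gene Itgae did not pass at -0.82 ± 0.18 (adjusted p = 0.0709; probe sets from -1.93 to 0.004) and -0.26 ± 0.07 (adjusted p = 0.117), and did without OT-1 replicate 1, at -0.96 (0.0227) and -0.32 (0.0237). Of 19 inhibitory receptors and ligands, 2 were higher and 4 lower (4 and 4 adjusted over the list alone; 2 and 7 without OT-1 replicate 1; camera adjusted p = 0.557), with Cd200, a ligand that restrains myeloid cells, higher by 3.06 ± 0.21 and Lag3 and Cd244a lower. Without OT-1 replicate 2, Lag3 did not pass (adjusted p = 0.0515), nor did Cd244a without CD8aa Treg replicate 1 (0.132).

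The cytokine list was the one list that passed as higher in CD8aa Tregs by camera at the preset correlation, while fry also placed the CD4 T cell markers higher (adjusted p = 0.0324). Of 30 cytokine genes, 6 were higher and 0 lower, and the same counts held adjusted over the list alone, against 10 and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0208; adjusted p = 0.424 with an estimated correlation; 8 and 2 without OT-1 replicate 1). Csf2, encoding GM-CSF, was higher by 2.81 ± 0.23 (adjusted p = 0.00502), Csf1 (M-CSF) by 2.07 ± 0.38 and Tnf by 1.75 ± 0.29. The median of the cytokine list was 0.01 and its mean 0.33, so its call rests on some of its members. Without CD8aa Treg replicate 4 the list did not pass (adjusted p = 0.0612). Csf1 and Tnf did not pass in 5 of the 6 leave-one-out fits (highest adjusted p = 0.158 without OT-1 replicate 2 and 0.128 without CD8aa Treg replicate 1), with differences of 1.83 to 2.47 and 1.58 to 2.03. Ifng did not pass at -1.16 ± 1.05 (adjusted p = 0.711). It was lower by -2.32 without OT-1 replicate 1 (adjusted p = 0.000357) and stood at 1.17 with the spike-in split as a term, a fit that rests on the low value of OT-1 replicate 1.

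Of 31 cytokine receptor genes, 1 was higher and 3 lower (3 and 7 adjusted over the list alone; 4 and 9 without OT-1 replicate 1; camera adjusted p = 0.0893, and 0.0458 with the spike-in split as a term). Tgfbr3 (betaglycan) was higher by 3.85 ± 0.17 over probe sets from 1.37 to 6.33, and Il2ra and Il21r (-1.19 ± 0.20) were lower. Il21r did not pass without OT-1 replicate 2 (adjusted p = 0.141). The cytokine receptor list also passed as lower without OT-1 replicate 3 (camera adjusted p = 0.0497). Of 34 transcription factors of T cell fates, 2 were higher and 4 lower (2 and 6 adjusted over the list alone; 4 and 11 without OT-1 replicate 1; camera adjusted p = 0.101). Rora, a nuclear receptor gene of type 17 and innate-like lymphocytes, was higher by 2.34 ± 0.13, though its 9 probe sets ran from -0.004 to 5.12. Zeb2 and Bach2 were lower by -1.17 ± 0.17 (probe sets from -2.43 to -0.15) and -1.13 ± 0.14 (probe sets from -1.75 to -0.11), and without OT-1 replicate 2 neither passed (adjusted p = 0.101 and 0.0758). Zbtb16 (PLZF), the factor of invariant NKT cells, did not pass (0.04 ± 0.03, adjusted p = 0.722). Without OT-1 replicate 1 the factor list passed as lower (adjusted p = 0.00552; adjusted p = 0.28 with an estimated correlation).

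Of 33 chemokine receptor, homing and adhesion genes, 1 was higher and 4 lower (1 and 5 adjusted over the list alone; 1 and 9 without OT-1 replicate 1). The integrin genes Itgax (CD11c) and Itga1 were lower by -5.07 ± 0.78 and -4.37 ± 0.17 (Itga1 probe sets from -5.31 to -3.43), and S1pr1, the receptor for exit from lymph nodes, by -3.59 ± 0.33. Camera placed this list lower (adjusted p = 0.019; adjusted p = 0.424 with an estimated correlation), but not in 2 of the 6 leave-one-out fits (highest adjusted p = 0.073, without OT-1 replicate 2) or with the spike-in split as a term (adjusted p = 0.381). The median of the homing list was -0.002 and its mean -0.55, so the call rests on some of its members. Itgax did not pass without OT-1 replicate 2 (adjusted p = 0.114). Of 17 chemokines, 0 were higher and Ccl5 was lower (-0.88 ± 0.07; 0 and 2 adjusted over the list alone, 1 and 3 at an unadjusted p under 0.05, 2 and 4 without OT-1 replicate 1; camera adjusted p = 0.18, and 0.0097 with the spike-in split as a term). Of 14 naive and central memory genes, 1 was higher and 3 lower (2 and 3 adjusted over the list alone; 2 and 5 without OT-1 replicate 1; camera adjusted p = 0.155). In that list Slamf6 was higher by 1.80 ± 0.10 over probe sets from -0.03 to 2.92, and S1pr1 and Bach2 were lower, Bach2 not without OT-1 replicate 2 (adjusted p = 0.0758).

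Sensors of microbial products went both ways. Of 23 Toll-like and other pattern recognition genes, 3 were higher and 1 lower (4 and 3 adjusted over the list alone; 4 and 4 without OT-1 replicate 1; camera adjusted p = 0.557). Tlr1 was higher by 1.61 ± 0.16, the DNA sensor gene Aim2 was higher by 1.11 ± 0.19, and Nod1 was lower by -0.67 ± 0.08. Without OT-1 replicate 2, Aim2 (adjusted p = 0.152) and Nod1 (0.0664) did not pass.

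The type I interferon response was lower in CD8aa Tregs. Of 26 genes, 0 were higher and 6 lower (0 and 10 adjusted over the list alone, 0 and 15 at an unadjusted p under 0.05, 0 and 19 without OT-1 replicate 1). Its median was -1.28 (camera adjusted p = 1.77e-08; adjusted p = 0.424 with an estimated correlation). Rtp4 was lower by -3.23 ± 0.45 over probe sets from -6.14 to -0.33, Ifit3 by -1.82 ± 0.18 and Gbp3 by -1.67 ± 0.25. Rtp4 did not pass without CD8aa Treg replicate 2 (adjusted p = 0.091), nor Gbp3 without OT-1 replicate 2 (0.111). OT-1 replicate 1 lay at least 1 below both other OT-1 arrays for 13 of the 26 genes. With the spike-in split as a term, where OT-1 replicate 1 alone stands for OT-1, the median of the list was -0.33. That value restates how this array differed from the CD8aa Tregs.

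Class I presentation genes held differences in both directions. H2-D1, a classical class I heavy chain gene, was higher by 3.33 ± 0.05 (adjusted p = 0.000107), but its 9 probe sets ran from -0.13 to 10.10. With probe sets whose identifiers end in _x_at or _s_at left out, 0 class I genes were higher and 1 was lower. H2-D1 thus did not pass as higher there, and its mean rests on some of its probe sets. H2-Q10 was lower by -3.40 ± 0.10 and Calr, which encodes a chaperone of class I folding, by -0.39 ± 0.06. Variants of strain or donor in the H2 complex, a candidate explanation given below, cannot be told apart here from changes in expression. H2-D1, H2-Q10 and the class II gene H2-Ab1 are thus not read as traits of regulatory cells. Of 17 genes, 1 was higher and 2 lower (1 and 3 adjusted over the list alone). The median was -0.20 (camera adjusted p = 0.0089; adjusted p = 0.424 with an estimated correlation). The call ended without OT-1 replicate 2 (adjusted p = 0.0656) and with the spike-in split as a term (adjusted p = 0.506), and Calr did not pass without OT-1 replicate 2 (0.134). Of 10 class II genes, 0 were higher and H2-Ab1 was lower (-1.85 ± 0.29, probe sets from -2.95 to -0.86, also over the list alone and at an unadjusted p under 0.05; camera adjusted p = 0.142), but not without OT-1 replicate 2 (adjusted p = 0.121). OT-1 replicate 1, the array with macrophage markers, stood above every other array for H2-Eb1 (2.58), Cd74 (2.15) and H2-Aa (1.80). Without it 2 class II genes were higher and 3 lower. In the fit with the spike-in split as a term, where this array alone stands for OT-1, 0 were higher and 4 lower (camera adjusted p = 0.00418), which restates its values.

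Glycolysis was the list whose values turned most on the OT-1 array used. With all arrays 0 of its 19 genes passed (limma), also over the list alone, while 1 was higher and 6 were lower at an unadjusted p under 0.05 (fry adjusted p = 0.199), and Slc16a3, a lactate transporter gene, stood at -2.57 ± 1.13 (adjusted p = 0.314). Without OT-1 replicate 1, 17 of 19 were lower, with Slc16a3 lower by -3.81 (adjusted p = 0.00252). The median over all arrays was -1.23 (camera adjusted p = 4.49e-05; adjusted p = 0.503 with an estimated correlation). The call ended with the spike-in split as a term (median -0.08, adjusted p = 0.506). OT-1 replicate 1 lay at least 1 below both other OT-1 arrays in 14 of the 19 genes.

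Immediate early and activation genes followed the same arrays. Of 24, 1 was higher and 1 lower (1 and 1 adjusted over the list alone; 2 and 12 without OT-1 replicate 1). Ier3 was higher by 1.22 ± 0.09 and Jun lower by -1.05 ± 0.13, Jun not without OT-1 replicate 2 (adjusted p = 0.0766). The median was -0.34 (camera adjusted p = 0.0115; adjusted p = 0.563 with an estimated correlation). The call ended without OT-1 replicate 2 (adjusted p = 0.152), under quantile normalization (0.0553) and with genes spanning at least 0.1 (0.0567), and with the spike-in split as a term camera placed the list higher (adjusted p = 0.0458). OT-1 replicate 1 lay at least 1 below both other OT-1 arrays in 11 of these genes.

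**Figure D2:**
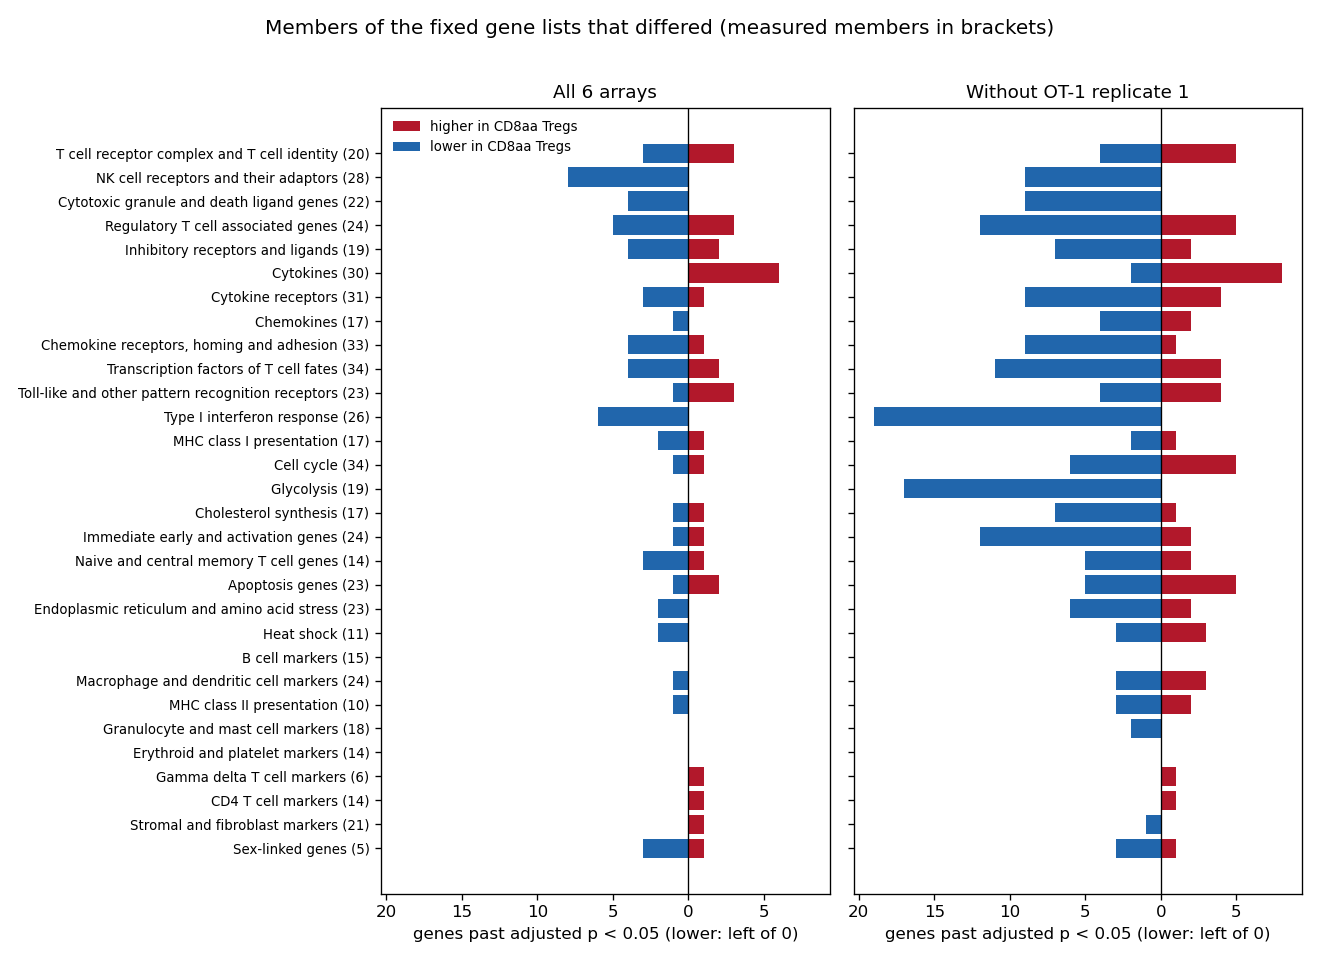
Bars count the members of each gene list that passed an adjusted p of 0.05, higher in CD8aa Tregs to the right in red and lower to the left in blue, with measured members in brackets. The left panel uses all 6 arrays and the right panel leaves out OT-1 replicate 1, which takes glycolysis from 0 to 17 lower genes and the interferon list from 6 to 19.

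Of 34 cell cycle genes, 1 was higher and 1 lower (1 and 1 adjusted over the list alone; 5 and 6 without OT-1 replicate 1; camera adjusted p = 0.381). Pcna, the sliding clamp of DNA replication, was lower by -0.90 ± 0.04. Tyms, a nucleotide synthesis gene, was higher by 0.27 ± 0.04 over probe sets from 0.01 to 0.70. It did not pass without CD8aa Treg replicate 2 (adjusted p = 0.115) or with the widest probe set of each gene. Without OT-1 replicate 1 the cell cycle list passed as lower (adjusted p = 0.0203; adjusted p = 0.633 with an estimated correlation), but as higher with the spike-in split as a term (adjusted p = 0.0232). Of 17 cholesterol synthesis genes, Hsd17b7 was higher by 2.04 ± 0.08 over probe sets from 0.04 to 3.73 and Fdft1 lower by -0.33 ± 0.05 over probe sets from -0.48 to 0.001 (1 and 2 adjusted over the list alone; 1 and 7 without OT-1 replicate 1). Fdft1 did not pass without CD8aa Treg replicate 1 (adjusted p = 0.108). Camera placed this list lower (adjusted p = 0.0499; adjusted p = 0.578 with an estimated correlation), but not in 4 of the 6 leave-one-out fits (highest adjusted p = 0.338, without CD8aa Treg replicate 2), under any of 4 other scalings (highest adjusted p = 0.143) or with the spike-in split as a term (adjusted p = 0.795).

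Stress genes that passed over all 6 arrays were lower in CD8aa Tregs, and without OT-1 replicate 1 some were higher. Of 23 endoplasmic reticulum and amino acid stress genes, 0 were higher and 2 lower (0 and 3 adjusted over the list alone, 2 and 6 at an unadjusted p under 0.05, 2 and 6 without OT-1 replicate 1): the chaperone gene Hspa5 by -0.57 ± 0.05 and the asparagine synthetase gene Asns by -0.31 ± 0.05. Camera placed the list lower (adjusted p = 0.0115; adjusted p = 0.424 with an estimated correlation), but not without OT-1 replicate 2 (adjusted p = 0.0603) or with genes spanning at least 0.1 (0.0687). Asns did not pass without CD8aa Treg replicate 1 (adjusted p = 0.145). Of 11 heat shock genes, 0 were higher and 2 lower (0 and 2 adjusted over the list alone, 1 and 3 at an unadjusted p under 0.05, 3 and 3 without OT-1 replicate 1; camera adjusted p = 0.155), Bag3 by -3.19 ± 0.08 and Dnajb1 by -0.44 ± 0.07, Dnajb1 not without OT-1 replicate 3 (0.116). Of 23 apoptosis genes, 2 were higher and 1 lower (4 and 2 adjusted over the list alone; 5 and 5 without OT-1 replicate 1; camera adjusted p = 0.743), with Casp1 at 1.34 ± 0.12, Birc2 at 0.81 ± 0.08 and Bid at -1.01 ± 0.10 (probe sets from -2.16 to 0.01).

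Sex-linked genes separated the groups on all 6 arrays. Beside Xist, the Y-linked genes Eif2s3y (-3.24 ± 0.05) and Kdm5d (-1.90 ± 0.03) were lower in CD8aa Tregs, over probe sets from -6.50 to 0.01 and from -4.75 to 0.003. Xist higher and Y-linked genes lower go with a difference in donor sex between the groups. Donor sex cannot be told apart from the kind of cell on these arrays, so these genes are not read as traits of regulatory cells. Of the 5 sex-linked genes, 1 was higher and 3 lower, also over the list alone. Camera placed the list lower (adjusted p = 0.0115; adjusted p = 0.424 with an estimated correlation), but not without OT-1 replicate 1 (adjusted p = 0.0623) or under quantile normalization (0.0809), and its median (-1.72) and mean (0.17) differed in sign.

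Markers of other cell types passed rarely between the groups. None of the 15 B cell, 18 granulocyte and mast cell or 14 erythroid and platelet markers passed, also over each list alone (limma; camera adjusted p = 0.592, 0.592 and 0.372, fry 0.92, 0.422 and 0.717). At an unadjusted p under 0.05, 1 granulocyte and mast cell marker was higher, 1 was lower, and 0 of the B cell, erythroid and platelet markers passed. The widest ranges were those of Ly86 (-0.27, adjusted p = 0.558), Cpa3 (adjusted p = 0.226) and Gp9 (0.27, adjusted p = 0.708). Cpa3, a mast cell protease gene, was lower without OT-1 replicate 1 (-4.14, adjusted p = 0.0129), 1 of 2 lower granulocyte and mast cell markers in that fit. Of 24 macrophage and dendritic cell markers, 0 were higher and Itgax was lower (0 and 2 adjusted over the list alone, 1 and 3 at an unadjusted p under 0.05, 3 and 3 without OT-1 replicate 1; camera adjusted p = 0.531), but not without OT-1 replicate 2 (adjusted p = 0.114). Of 21 stromal markers, Pecam1 was higher at 1.82 ± 0.33 (0 over the list alone; 0 higher and 1 lower without OT-1 replicate 1; camera adjusted p = 0.645), but not without OT-1 replicate 3 (0.148). In the granulocyte, macrophage and stromal lists the median lay just above 0 (0.01, 0.02 and 0.01) and the mean below it (-0.18, -0.42 and -0.07), while camera placed the granulocyte and stromal lists higher and the macrophage list lower, none past the threshold over all 6 arrays.

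On OT-1 replicate 1 alone, 7 of the 24 macrophage and dendritic cell markers stood at least 1 above every other array. They were C1qa, C1qb, C1qc, Csf1r, Lyz1, Lyz2 and Mpeg1, with C1qb at 3.30. Tyrobp and Fcgr3, which NK and myeloid cells share, stood at 3.33 and 3.35 there. The same array was the low one of the OT-1 arrays for glycolysis, interferon response, immediate early and cytotoxic genes, so these markers moved with those lists too. Batf3 (-1.55) stood at least 1 below every other array there, and Itgax and Cd68 at least 1 below both other OT-1 arrays. Where this array alone stands for OT-1, with the spike-in split as a term, the macrophage list was placed lower in CD8aa Tregs (1 higher, 9 lower; camera adjusted p = 2.72e-05), which restates the markers of this array.

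**Figure D3:**
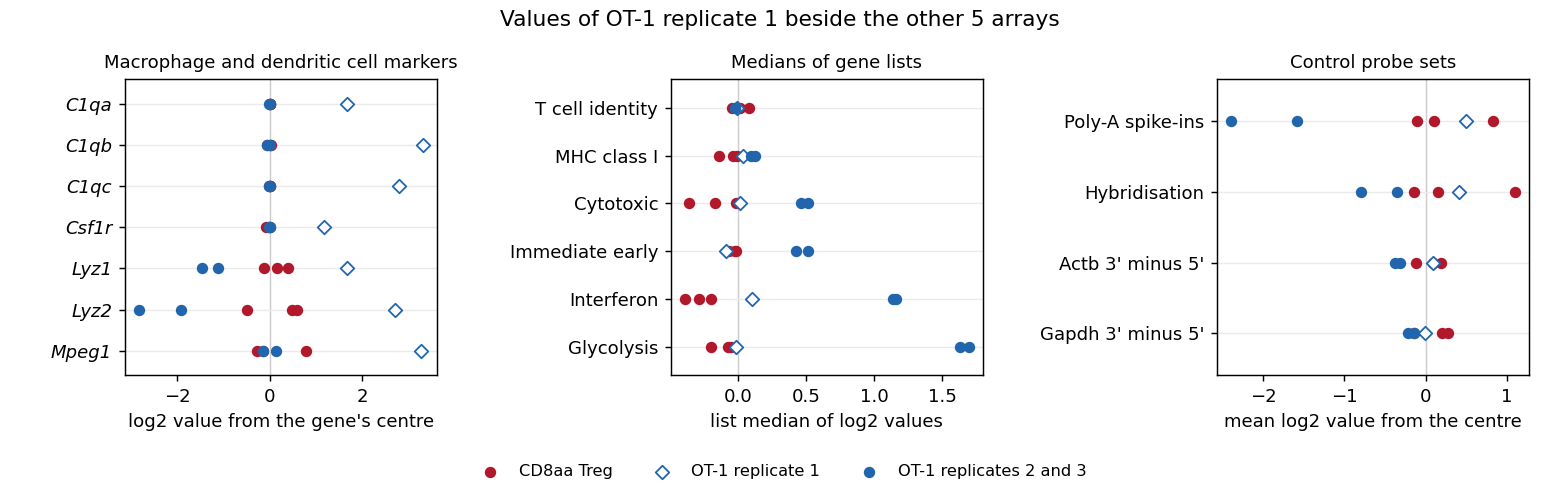
Each point is 1 array, with OT-1 replicate 1 as an open diamond, OT-1 replicates 2 and 3 in filled blue and CD8aa Tregs in red. The left panel gives log2 values of macrophage and dendritic cell markers, the middle panel the medians of gene lists, and the right panel mean log2 values of array controls, each from its centre over the arrays. OT-1 replicate 1 stands at 3.30 for C1qb, and at 0.49 for the poly-A spike-ins against -1.58 and -2.39 on OT-1 replicates 2 and 3.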

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

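The tests of OT-1 replicate 1 and of its macrophage markers were chosen only after these results were seen.

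The poly-A spike-in controls, which are not transcripts of the cells, stood higher on the CD8aa Treg arrays than on the OT-1 arrays by 1.43 (log2), at 0.27 ± 0.48 against -1.16 ± 1.49 (SD, n = 3 each). The difference was not tested, and OT-1 replicate 1 (0.49) lay within the range of the CD8aa Tregs. For Actb, the 3' minus the 5' probe set stood at 0.09 on OT-1 replicate 1 against -0.38 and -0.32 on OT-1 replicates 2 and 3 (0.05 against -0.20 between the group means). Among 10092 probe sets without a single gene name, 324 passed over all probe sets (limma, Benjamini-Hochberg), and 121 of them were at least 2-fold higher and 111 at least 2-fold lower in CD8aa Tregs. The largest differences were 8.69 and -10.80.

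OT-1 replicate 1 was nearer the CD8aa Treg mean than the mean of OT-1 replicates 2 and 3 in 46.6% of the 953 genes that differed at least 2-fold without it, and it stood at least 1 above every other array in 43 genes and at least 1 below in 41, against at most 8 and 3 on any other array. A swap with a CD8aa Treg sample is argued against by Xist, at which this array lay -7.36 from the CD8aa Treg mean and 0.53 from the other OT-1 arrays, and no CD8aa Treg array stood as low as an OT-1 array. Dilution of its T cell RNA by other cells on the scale of the glycolysis median, which differed by -1.63, is argued against. The median of the T cell receptor complex list on this array differed by -0.007 from OT-1 replicates 2 and 3 (95% bootstrap interval over genes -0.22 to 0.18). A smaller share of other cells could leave the median inside that interval, so it stays open. A handling batch stays open, since the poly-A spike-ins differed by 2.48 between this array and the other OT-1 arrays, against a range of 0.93 over the CD8aa Treg arrays, although the hybridisation controls differed by 0.98, within their CD8aa Treg range of 1.24. A different state of that culture and a sample from outside the series stay open too and were not tested.

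On OT-1 replicate 1, 7 of 24 macrophage and dendritic cell markers stood at least 1 above every other array, against a mean of 0.062 in 10000 random draws of as many genes (share 0.0001, the smallest they can give). Of the 24, 3 are held by another list, but 0 of those 7. Per the labels, the cells were grown with antigen-presenting cells, and carry-over of antigen-presenting cells in that culture cannot be told apart from expression by the T cells themselves, because both would give this count of 7. Carry-over of B cells in that culture is argued against as their source, since 0 of 15 B cell markers stood that high, with Ighm at 0.06 and Cd79a at 0.01, and Ly86 highest at 0.62.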

How the results depend on the processing

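The widest probe set, the filter on range, robust variances, median centring and the spike-in split were chosen after the data were seen. With 1 array left out, 523 to 3129 genes passed, 277 to 953 of them at least 2-fold, and 6 to 13 of 30 lists. The highest values of all 3 came without OT-1 replicate 1, where the groups coincide with the spike-in split. The lower counts come with fewer samples. Array weights gave 3848 genes and 899 at least 2-fold, with the largest weight on CD8aa Treg replicate 1 (4.21) and the smallest on OT-1 replicate 1 (0.366). An adjusted p under 0.01 left 380 and 244 by construction, and testing all 45037 probe sets that are not controls gave 1827 and 1044, with more units and no averaging within genes. Leaving out genes spanning under 0.1 gave 7 lists of 27. Camera with an estimated correlation called 0 lists of 30 (2 at an unadjusted p under 0.05), while fry called 12, of which 8 were among the 12 of camera, in the same direction. Only replicate numbers 1 and 2 occur in both groups. Deviations of same-numbered arrays from their group means correlated at 0.001 and 0.172 across genes, so the numbers were not taken to pair arrays. With the replicate block, 202 genes passed, 202 at least 2-fold, and 10 lists. That block ended the call of 35 named genes and of the regulatory and cholesterol synthesis lists (camera adjusted p = 0.0531 and 0.0806). Other scalings and probe set rules kept the gene counts within 1.5 times of 1214 and 473. With the spike-in split as a term, 1361 genes, 496 at least 2-fold, and 12 lists passed. Of the first 12, 6 passed in the same direction and 1, the immediate early list, in the opposite one. Ifng then turned to 1.17 because OT-1 replicate 1 lies below the CD8aa Tregs. Over 81 named genes and all alternatives, 1237 of 1456 values kept side and sign, 203 no longer passed, 15 newly passed and 1 (Ifng) reversed. Not run, because the deposited values hold no level, were the brightest probe set, an added constant, a filter on mean level and an intensity trend. What lies below background on these arrays cannot be read from centred values.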

Other observations

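Of the tests here, those of the H2 complex and of gene families were chosen after a result was seen. The test of neighbouring pairs was set before, but the bounds of the H2 complex, which it leaves out, were redrawn after a first result.

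Some genes outside the naming rule, chosen after their values were seen, add to the description. They stand for no group. Those compared between the groups are all members of the neighbouring pairs counted below, so they are not findings independent of that count. In CD8aa Tregs, Trim30d was lower by -5.21, Trim30a by -1.29, Trim5 by -3.35, Trim12a by -2.85, Trim34a by -2.71, Ifi209 by -3.58 and Ifi213 by -3.53, while Aim2, the neighbour of Ifi213, was higher by 1.11. The antiviral deaminase gene Apobec3 was lower by -3.32. The purinergic receptor genes P2ry13 and P2ry14 were lower by -2.77 and -1.79, and their neighbour Gpr171 by -1.66. Mme, a membrane metalloprotease gene, was lower by -5.11. The sialyltransferase genes St6galnac1 and St6galnac2 were higher by 3.06 and 2.44. On OT-1 replicate 1, the granzyme genes Gzmd, Gzmg, Gzme and Gzmc stood at -7.46, -5.50, -5.38 and -3.99, at least 1 below every other array.

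Genes that neighbour each other in assembly GRCm38.p6 differed together. With the H2 complex and the sex chromosomes left out, 40 neighbouring pairs both differed at least 2-fold, 34 of them with the same sign, against a mean of 11.6 and a highest of 26 in 10000 shuffles (share 0.0001, the smallest they can give). In the H2 complex, 8 of 123 genes (6.5%) differed at least 2-fold, against 2.58% of the others (one-sided Fisher's exact p = 0.0153). Gene families side by side are argued against as the whole cause, since 30 pairs whose symbols do not share their first 3 letters remained, against a mean of 10.64 (share 0.0001). A candidate explanation is that the groups carry different variants in blocks of the genome, by strain or donor. Shared control of unrelated neighbours stays open, and so does a difference between the kinds of cell; neither was tested.

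The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split alone, 1 of the 10, gave as many genes (1214, against at most 0 in the others), as many genes at least 2-fold (473, against at most 0) and as many lists (12, against at most 11). The 11 lists came in the split of CD8aa Treg replicates 1 and 2 with OT-1 replicate 1 against the rest, and in that of CD8aa Treg replicate 1 with OT-1 replicates 2 and 3. Both keep OT-1 replicates 2 and 3 together and apart from OT-1 replicate 1, so the count of lists follows a structure among the arrays beside the groups, which is also that of the spike-ins. With the spike-in split as a term, 12 lists passed. Of the first 12, 6 were among them in the same direction and 1, the immediate early list, in the opposite one.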
